A study of Homo sapiens with 18 samples.

How the data were processed

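RNA from cultured MCF-7 sublines was hybridised to 18 Affymetrix 3′ whole-genome arrays, in 5 groups taken from the sample titles and characteristics. The deposited values are log2 expression values per probe set, made by the authors with Partek and RMA per the submitters' processing notes. RMA corrects the background, equalises the distributions of probe signals across arrays and summarises each probe set by median polish. No version, setting or order of steps is given in the sources used here, nor whether all arrays were normalised in 1 run. Scanner output was not used here, so background levels and scan batches were not analysed. The log2 scale was checked from the values, which ran from 2.87 to 15.16 with array medians of 5.44 to 5.55. No 2 arrays held identical values, and Pearson's r across probe sets between pairs of arrays ran from 0.936 to 0.995.

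The table held 54675 probe sets, of which 62 were Affymetrix control probe sets. The supplied platform annotation paired 41091 probe sets with 1 gene symbol and 1801 with several, and it listed no gene for 11777. Entrez identifiers of 41037 of the 41091 probe sets matched the supplied RefSeq gene table, and no symbol needed updating. Only probe sets with 1 gene symbol were used for genes, which left 19775 genes. Where a gene had several probe sets (10523 genes), the one with the highest mean over the 18 arrays was used, and probe sets whose name ends in _x_at, which can hybridise with related transcripts, were used only for the 419 genes that had no other. The number of arrays limits the precision of every value.

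Each gene was fitted with limma (version 3.58.1 in R 4.3.3), with a mean for each of the 5 groups, a spread shared by all groups and moderated variances (lmFit and eBayes). The contrasts were the mean of the 4 resistant lines, with equal weight per line, minus the parental line, and each resistant line minus the parental line. Differences among the resistant lines were tested with limma's F-test and pairwise. P-values were adjusted by the Benjamini-Hochberg method over all genes, a gene was called at an adjusted p under 0.05, and calls with a change of 2-fold or more (a log2 difference of at least 1) were counted again. Where the other probe sets of a gene are given, their adjusted p-values come from a separate fit over the 41091 probe sets with 1 gene symbol. Those values are not directly comparable with the ones adjusted over genes. Changes in the text are log2 differences, with ± giving the standard error of the fit unless SD is stated.

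Of 567 genes in 20 lists drawn from textbook knowledge, 515 had a usable probe set. Each list was compared with the other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the arrays. The fry test asked whether members moved, on balance, one way. List p-values were adjusted over the lists of a contrast. Members were counted as called over all genes and, separately, adjusted over the list alone.

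Named genes followed a rule. For the average of the lines these were the 10 largest rises and 10 largest falls among called genes with the same sign in each line and no overlap between resistant and parental arrays. For each line they were the 5 largest rises and 5 largest falls, and for the differences between lines the 10 genes with the widest range of line means among the 200 smallest F-test p-values. Each list contributed up to 3 called members with the largest change, per contrast described. ESR1, PGR, GREB1, TFF1, GATA3, FOXA1, EGFR, ERBB2, BCL2, CCND1, FYN, SNAI2, PDK4 and MKI67 were always named. The design, tests, lists, naming rule and the other settings, apart from those with the batch, were fixed before the data were examined, except where the text says otherwise.

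Control probe sets showed that the arrays fall into 2 batches of 9 which the labels do not name. After this was seen, every contrast was refitted with the batch as a block and within batch 2, and TamR1, TamR4 and their mean also within batch 1, where TamR7 and TamR8 have no array. Those values stand beside the unblocked ones. Other settings tried were quantile normalisation, median centring, filters on dim genes (mean log2 of at least 5 or 7), the mean of all probe sets of a gene, every probe set on its own, an intensity trend with robust variances, array weights, the replicate number as a block, each array left out, parental replicate 1 left out, 2 pooled groups, each line left out of the average, only 1 line with the parental line in the fit, a test beyond 2-fold (treat) and camera with an estimated correlation. Leaving out parental replicate 1 was chosen because its description calls the cells resistant, whereas its title and characteristics call them sensitive; the title and characteristics were followed.

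The fit was tested on simulated data for the average contrast, with 19775 genes of which 200 were changed. Without a batch, the unblocked fit recovered 62.7% of genes changed by 0.5 log2 units and 100% of those changed by 1 or 2, and it called 10 unchanged genes. The blocked fit recovered 35.8%, 92.5% and 100%, and it called 3 unchanged genes. With a simulated batch of the size seen in the real arrays, the unblocked fit called 2764 unchanged genes, 96 of them at 2-fold or more, while the blocked fit called 3. Overlaps between lines, which share their parental arrays, were set beside 50 simulated data sets without any line effect, beside 50 more with a batch shift of the fitted size, beside independent lists, and beside 20 draws in which the parental arrays were split between the lines. Gene order along the genome came from the supplied RefSeq table for GRCh38.p14 and was used only for which genes neighbour each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.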

Results

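Gene expression was compared between tamoxifen-resistant and tamoxifen-sensitive sublines of MCF-7, an estrogen receptor positive breast carcinoma cell line. The sensitive subline MCF-7/S0.5, called the parental line here, grows in low serum and was represented by 8 arrays. TamR1, TamR4, TamR7 and TamR8 were derived from it under prolonged exposure to tamoxifen, which competes with estrogen for its receptor, and were represented by 3, 3, 2 and 2 arrays. The resistant cells received 1e-06 M tamoxifen ahead of RNA extraction, and the labels state no such exposure for the parental cells, so resistance and presence of the drug varied together in every comparison. The submitters describe the arrays of a group as biological replicates without saying that cultures were handled separately, so p-values cover only the spread between these arrays.

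Control probe sets divided the arrays into 2 batches that the labels do not name. The 18S ribosomal RNA control read 13.27 to 13.67 on the 9 arrays of batch 1, which were parental replicates 1 to 7, TamR1 replicate 1 and TamR4 replicate 1. It read 9.17 to 10.83 on the 9 arrays of batch 2, which were parental replicate 8 and the remaining arrays of the resistant lines. The actin control was 2.02 to 4.12 log2 units brighter at its 3′ end than at its 5′ end in batch 1, where parental replicate 1 (4.12) and parental replicate 2 (3.07) were highest, and 0.25 to 0.63 units brighter in batch 2. With the batch as a term in the fit, limma called a batch difference for 4012 genes, of which 312 differed by 2-fold or more. TamR7 and TamR8 have arrays in batch 2 only, where the parental line has a single array. Counts of called genes, medians of gene lists and most named genes are therefore also given with the batch as a block, and most list medians and the leading genes within batches as well. A difference given without such a value comes from the fit without the batch, and pairs of resistant lines were not compared within batches. Batch 1 holds TamR1 and TamR4 with 1 array each, so every batch 1 value of the average is the mean of these lines alone and is not the same contrast as the average of all 4 lines.

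**Figure D1:**
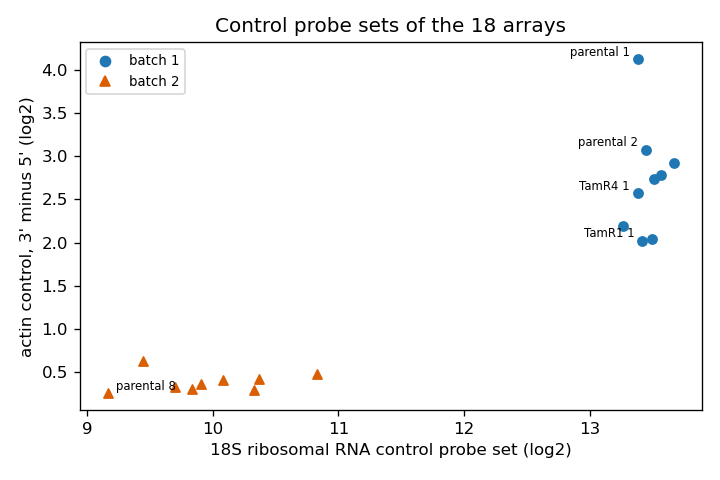
The 18 arrays by their 18S ribosomal RNA control probe set (horizontal axis, log2) and the difference between the 3′ and 5′ actin control probe sets (vertical axis, log2), with batch 1 as blue circles and batch 2 as orange triangles. Batch 1 lies at 13.27 to 13.67 on the horizontal axis and batch 2 at 9.17 to 10.83, and parental replicate 1 stands highest at 4.12 on the vertical axis.

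The main comparison asked which genes differ between resistant and sensitive cells. The average of the resistant lines weighs the 4 lines equally. In it, transcripts of GREB1 and PGR, both classical targets of the estrogen receptor, fell to near the lower end of the measured range. CD36 and SOX2 rose by 4 log2 units or more in the probe sets used. CD36 is a fatty acid and lipoprotein receptor, and SOX2 a transcription factor of pluripotent and progenitor cells. GREB1 stood at 10.27 ± 0.996 (SD, n = 8) in parental cells and 3.29 ± 0.091 (SD, n = 10) in resistant cells, a difference of -6.98 ± 0.306 (adjusted p = 2.68e-11, limma). Its values on the resistant arrays, 3.19 to 3.43, lie near the lowest value on any array (2.87) and were not shown to exceed background. The size of the fall was therefore not determined exactly, and no fold is given. Other genes also had a mean under 5 in 1 of the groups compared. Among the genes named below these were the resistant arrays for PGR, IL20, ELOVL2, MALRD1, PLXDC2, SOX9 and PRAME, and the parental arrays for CD36, PPP1R9A, GOLM1, ATP10D, SNAI2, PDK4, AGR3, KRT15, SAMD9, KRT13, LIMCH1 and SLC6A14. In single lines they were IGF1R in TamR4, TamR7 and TamR8, NPY1R, IL24 and HERC5 in TamR1, IL24 in TamR7, PCDH7 in TamR4, and SLITRK6 and ANKRD30A in TamR8. None of these values was shown to exceed background, so the sizes of these differences were not determined exactly and the order of the largest ones is not settled. PGR, the progesterone receptor, differed by -5.47 ± 0.216 (adjusted p = 7.46e-12). CD36 rose from 4.46 ± 0.19 (SD, n = 8) to 9.29 ± 1.44 (SD, n = 10), and the equally weighted lines gave a difference of 4.96 ± 0.259 (adjusted p = 3.29e-10). SOX2 rose by 4.15 ± 0.329 (adjusted p = 8.46e-08). By line, CD36 was lowest in TamR1 (3.17) and SOX2 in TamR7 (2.61). With the batch as a block these differences were -6.83, -5.51, 5.07 and 4.59, and within batches 1 and 2 they were -7.03 and -6.49 for GREB1, -5.18 and -5.81 for PGR, 4.43 and 5.01 for CD36, and 5.05 and 4.32 for SOX2. Every resistant array lay on the same side of every parental array for each of these genes, a separation that the naming rule required of the largest changes. Dimmer probe sets of SOX2 were at 1.43, 0.67 and -0.07 (1.49, 0.51 and -0.27 with the block). Dimmer ones of CD36 were at 3.66, 2.34, 0.26 and -0.06 (3.6, 2.76, 0.43 and 0.13 with the block). The sizes of both rises therefore depend on the probe set. For SOX2, parental replicates 3 and 4 read 6.49 and 6.37, near TamR7 replicate 1 (6.93), against 4.38 to 4.77 on the other parental arrays.

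The other leading falls, many of them into this dim range, were those of IL20, a cytokine of the IL-10 family (-5.07), GFRA1, the co-receptor for glial cell line-derived neurotrophic factor (-4.96), ELOVL2, an elongase of polyunsaturated fatty acids (-4.72), and IGF1R, the receptor for insulin-like growth factor 1 (-4.58). MALRD1 fell by 3.94, the collagen gene COL12A1 by 3.57, RERG, a small GTPase that estrogen induces, by 3.48, and PLXDC2 by 3.37. Their adjusted p-values ran from 4.24e-14 for GFRA1 and ELOVL2 to 5.19e-10 for COL12A1. Among the rises, PGM2L1 (3.28), TIMP2, an inhibitor of metalloproteinases (3.15), SH3BGRL (3.09), EPAS1, which encodes hypoxia-inducible factor 2α (3.07), and PPP1R9A (3.05) followed CD36 and SOX2. GOLM1, a Golgi membrane protein, rose by 3.0, ATP10D by 2.97 and ENTREP1 by 2.86. The adjusted p-values of these rises reached 5.1e-08 for SH3BGRL. All 20 of these genes were also called with the batch as a block, where the rises ran from 2.85 for GOLM1 to 5.07 for CD36 and the falls from -3.25 for RERG to -6.83 for GREB1. Within batch 1 (TamR1 and TamR4) the rises ran from 2.49 for PPP1R9A to 5.05 for SOX2 and the falls from -2.75 for RERG to -7.03 for GREB1. Within batch 2 the rises ran from 2.82 for GOLM1 to 5.01 for CD36 and the falls from -3.07 for PLXDC2 to -6.49 for GREB1.

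Over all 19775 genes, limma called 2307 higher and 3316 lower in the average of the resistant lines, of which 389 rose and 231 fell by 2-fold or more. With the batch as a block 1613 were higher and 771 lower, of which 387 rose and 105 fell by 2-fold or more. Of the 620 genes called at 2-fold or more, 338 (54.5%) were called at 2-fold or more in the same direction with the block, 242 higher and 96 lower. The resistant and parental arrays did not overlap for 239 genes called higher and 227 called lower with the same sign in each line, a separation that chance would give for 0.00457% of genes if all arrays were exchangeable and for at most 0.617% if arrays were exchanged only inside batches.

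**Figure D2:**
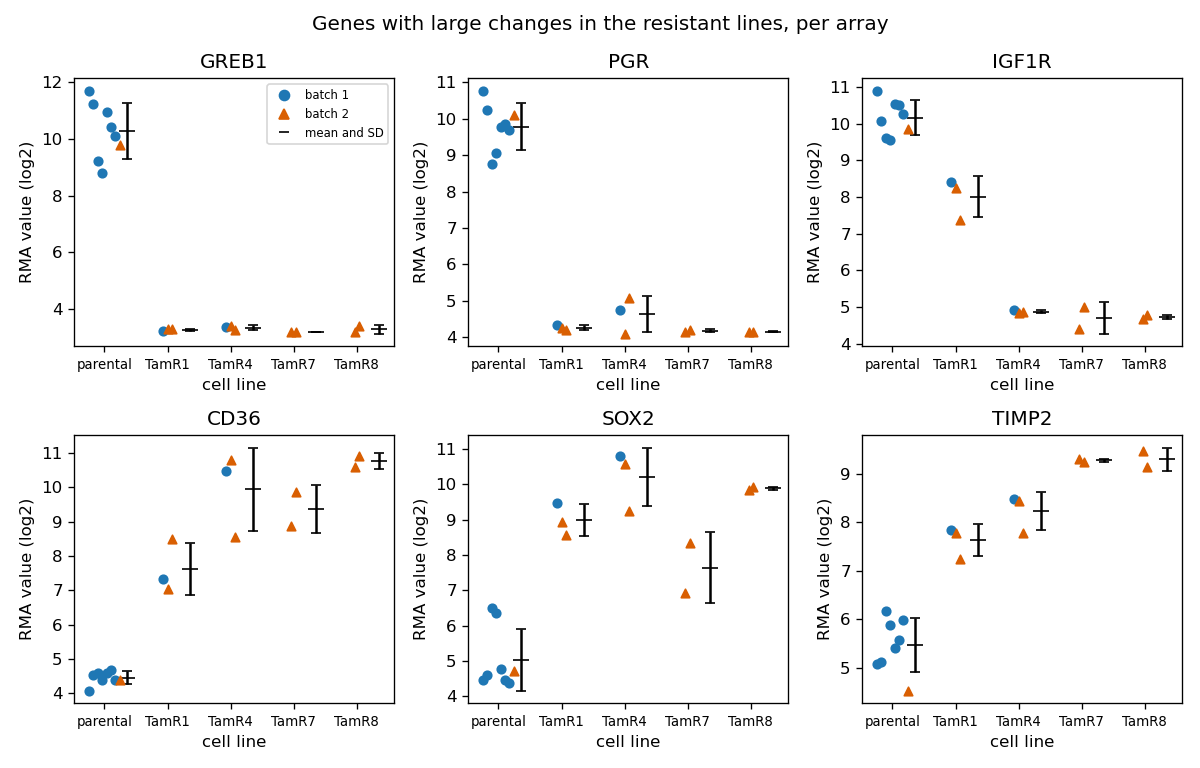
RMA log2 values of GREB1, PGR, IGF1R, CD36, SOX2 and TIMP2 on each of the 18 arrays, grouped by line, with bars giving the mean and SD of each group, blue circles for batch 1 and orange triangles for batch 2. GREB1 lies between 8.79 and 11.69 on the parental arrays and between 3.19 and 3.43 on the resistant arrays, and IGF1R lies between 7.38 and 8.40 in TamR1 but between 4.40 and 5.01 in the other resistant lines.

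Genes that estrogen induces in MCF-7 cells fell more often than they rose. Of 41 measured, 18 fell, 6 rose and 17 did not pass the test (19 and 6 adjusted over the list alone), and the list lay below other genes (median -0.31, camera adjusted p = 0.000656). The list's call was lost with an estimated correlation (adjusted p = 0.282). TFF1, a secreted trefoil peptide, fell by 2.11 ± 0.101 (adjusted p = 1.08e-10) and BCL2, an inhibitor of apoptosis, by 1.40 ± 0.158 (adjusted p = 4.79e-06). CCND1, which encodes cyclin D1, differed by -0.07 ± 0.134 (adjusted p = 0.733). The 5 members that rose both with and without the block, named here after their values were seen, were the keratin KRT13 (2.83), the small heat shock protein HSPB8 (1.20), FHL2 (0.95), the scaffold protein NHERF1 (0.91) and RAPGEFL1 (0.70). With the batch as a block the median was -0.24, TFF1 was at -2.12 and BCL2 at -0.99, and the list medians within batches 1 and 2 were -0.49 and -0.42.

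ESR1, which encodes estrogen receptor α, fell by 1.28 ± 0.084 (adjusted p = 7.27e-09), from 12.46 ± 0.106 (SD, n = 8) to 11.18 ± 0.414 (SD, n = 10). It remained among the bright genes of the array, with differences of -1.16 with the block and -1.12 and -1.22 within batches 1 and 2. The gene has 8 other probe sets, of which 2 differed in the same direction, and the mean of all its probe sets differed by -0.29 (adjusted p = 0.0834). With the block 6 of these 8 probe sets were lower, by -0.53 to -1.59. In TamR4 ESR1 lies in a run of 22 neighbouring genes with a median blocked difference of -0.55. In TamR7 it lies in a run of 18 with a median of -0.48, and in TamR1 and TamR8 in no such run. Luminal epithelial genes, which include ESR1, were higher on balance: 13 of 25 rose, 4 fell and 8 did not pass (14 and 4 adjusted over the list alone; median 0.26, camera adjusted p = 0.000137). AGR2, a protein disulfide isomerase of secretory cells, rose by 1.32 ± 0.156 (adjusted p = 8.32e-06; 1.41 with the block), and its relative AGR3 by 1.54 ± 0.164 (adjusted p = 2.47e-06; 1.88 with the block), mainly through TamR7 (4.20). The lineage factors GATA3 (-0.10, adjusted p = 0.348) and FOXA1 (0.74, adjusted p = 0.00599) differed less in these probe sets, and FOXA1 was at 0.22 (adjusted p = 0.539) with the block. The other probe set of FOXA1 was lower (-0.45, adjusted p = 0.0198; -0.12 with the block), so its direction is not settled. The 2 other probe sets of GATA3 were lower without the block (-0.91, adjusted p = 0.00348, and -0.39, adjusted p = 0.0332), and neither was called with it (-0.16 and -0.09). CLDN3, a tight junction protein, was at 2.00 without and 0.46 (adjusted p = 0.158) with the block. The list's blocked median was 0.22, its medians within batches 1 and 2 were 0.12 and 0.29, and the call held with an estimated correlation.

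Basal and myoepithelial genes rose in 8 of 18 cases and fell in 1, with 9 not passing (8 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.00191), a call lost with an estimated correlation (adjusted p = 0.0587). The list has 25 genes, of which KRT6A, KRT6B, KRT17, TP63, LAMC2, FOXC1 and COL17A1 had no usable probe set. Smooth muscle actin, ACTA2, rose by 1.89 ± 0.188 (adjusted p = 1.14e-06), the keratin KRT15 by 1.22 ± 0.147 (adjusted p = 1.11e-05) and P-cadherin, CDH3, by 1.18 ± 0.1 (adjusted p = 1.76e-07), with blocked values of 1.97, 1.44 and 1.02. The median was 0.34 with the block and 0.12 and 0.31 within batches 1 and 2. ACTA2 lies beside FAS and LIPA in a run of neighbouring genes in TamR4, TamR7 and TamR8. Mesenchymal genes did not move together: 3 of 25 rose and 4 fell, with 18 not passing (3 and 4 adjusted over the list alone; median -0.09, camera adjusted p = 0.916; -0.07 with the block and -0.03 and -0.10 within batches). SNAI2, a repressor of E-cadherin, rose by 1.68 ± 0.268 in the average (adjusted p = 0.000182, and 2.10 with the block). It was at 3.19 in TamR1 and 2.91 in TamR7, against 0.67 in TamR4 and -0.06 in TamR8. The calcium-binding protein S100A4 fell by 1.02 ± 0.136 (adjusted p = 3.12e-05, and -0.68 with the block).

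Among receptor tyrosine kinases and their ligands, 5 of 29 rose, 9 fell and 15 did not pass (6 and 9 adjusted over the list alone; median -0.15, camera adjusted p = 0.428). Besides IGF1R, the neuregulin receptor ERBB4 fell by 1.99 ± 0.165 (adjusted p = 1.38e-07; -1.60 with the block), and the ephrin receptor EPHA4 rose by 2.05 ± 0.191 (adjusted p = 5.96e-07; 1.63 with the block). EGFR was at -1.06 (adjusted p = 0.00201) without the block and -0.51 (adjusted p = 0.239) with it, but another of its probe sets was higher in both fits (0.57, adjusted p = 0.000323, and 0.41, adjusted p = 0.0408), so the direction of EGFR is not settled. INSR, the insulin receptor, was at -1.08 and -0.07 (adjusted p = 0.812). ERBB2, the receptor known as HER2, differed by 0.31 ± 0.124 (adjusted p = 0.0665; 0.25, adjusted p = 0.423, with the block), and a dimmer probe set of it was higher without the block (1.03, adjusted p = 0.00206) but not called with it (0.31, adjusted p = 0.289). Leaving out any 1 TamR4 array brought ERBB2 past the threshold, with adjusted p-values of 0.0328, 0.032 and 0.0351. The list's median was -0.07 with the block, and -0.06 and 0.10 within batches 1 and 2. In the SRC kinase list 2 of 10 genes rose and 2 fell, with 6 not passing (3 and 3 adjusted over the list alone; camera adjusted p = 0.511). FYN rose by 1.58 ± 0.108 (adjusted p = 1.41e-08; 1.48 with the block) and LYN by 1.75 ± 0.171 (adjusted p = 9.57e-07; 2.12 with the block), both with the same sign within each batch. The median of this list was -0.12, -0.03 with the block and 0.04 and 0.01 within batches, whereas its mean of 0.23 and its test pointed upward.

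Interferon-stimulated genes rose as a group. Of 37 measured, 34 rose and 3 did not pass (35 rose adjusted over the list alone), with a median of 1.47 and a camera adjusted p of 1.99e-23, a call lost with an estimated correlation (adjusted p = 0.102). IFI44L rose by 3.03 ± 0.649 (adjusted p = 0.00213), SAMD9, an antiviral factor, by 3.09 ± 0.332 (adjusted p = 2.83e-06) and IFI27 by 2.82 ± 0.516 (adjusted p = 0.000619). With the block 22 members rose and the median was 1.41, and IFI44L was at 2.85 (adjusted p = 0.0523). The medians within batches 1 and 2 were 1.38 and 0.62, and the list was 0.79 higher on the parental array of batch 2 than on those of batch 1, whereas batch 2 minus batch 1 was -0.42 inside TamR1 and -0.43 inside TamR4. Antigen presentation genes rose in 14 of 21 cases, with 7 not passing (18 rose adjusted over the list alone; median 0.73, camera adjusted p = 8.52e-15), and the call held with an estimated correlation (adjusted p = 0.0211). The immunoproteasome subunits PSMB8 and PSMB9 rose by 2.64 ± 0.266 (adjusted p = 1.4e-06) and 2.09 ± 0.265 (adjusted p = 1.77e-05), and HLA-C, one of a family of similar transcripts that can share probes, by 2.39 ± 0.216 (adjusted p = 3.9e-07), with blocked values of 2.90, 2.46 and 2.13. This list's median was 0.70 with the block and 0.63 and 0.60 within batches 1 and 2.

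**Figure D3:**
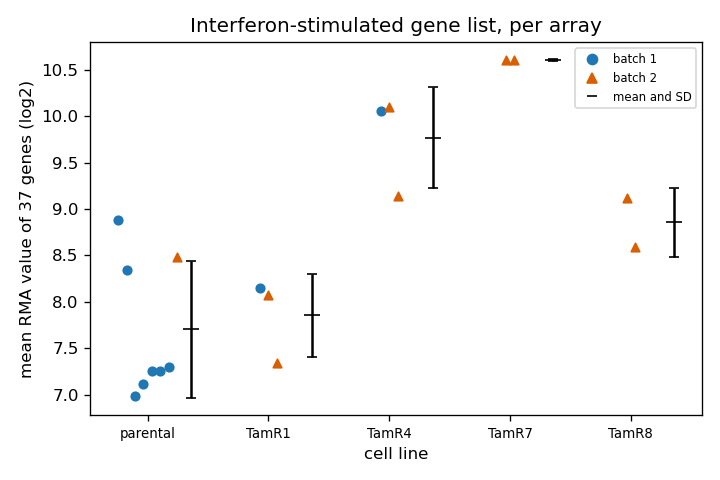
Mean RMA log2 value of the 37 measured interferon-stimulated genes on each array, by line, with bars for the group mean and SD, blue circles for batch 1 and orange triangles for batch 2. The parental arrays spread over 1.89 units, from 6.99 to 8.88, the TamR1 arrays lie inside that range, and the TamR7 arrays stand at 10.61 and 10.60.

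Cholesterol synthesis genes rose in 12 of 19 cases, with 7 not passing (16 rose adjusted over the list alone; median 0.46, camera adjusted p = 7.71e-10), and the call held with an estimated correlation (adjusted p = 0.0211). The list has 25 genes, of which HMGCR, CYP51A1, DHCR24, FDFT1, LDLR and PCSK9 had no usable probe set. The sterol reductase TM7SF2 rose by 1.78 ± 0.196 (adjusted p = 3.78e-06; 1.05 with the block), the desaturase SC5D by 1.42 ± 0.125 (adjusted p = 3.12e-07; 1.57 with the block) and the methylsterol oxidase MSMO1 by 1.21 ± 0.148 (adjusted p = 1.27e-05; 1.23 with the block). The median was 0.40 with the block, where 6 members rose, and 0.45 and 0.39 within batches 1 and 2. Among fatty acid synthesis genes 4 of 17 rose and 2 fell, with 11 not passing (5 and 3 adjusted over the list alone; median 0.14, camera adjusted p = 0.058; 0.17 with the block and 0.04 and 0.11 within batches). Without TamR7 replicate 1, parental replicate 2 or parental replicate 5 this list passed (adjusted p = 0.0272, 0.0467 and 0.0432). ACSL1, which activates long-chain fatty acids, rose by 1.12 ± 0.134 (adjusted p = 1.05e-05; 1.26 with the block). No list of this comparison kept an adjusted p under 0.05 when the batch was a block and the correlation was estimated as well, the lowest value being 0.0874.

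Cell cycle genes fell in 14 of 40 cases and rose in 3, with 23 not passing (14 and 3 adjusted over the list alone; median -0.23, camera adjusted p = 0.137). The thymidylate synthase gene TYMS fell by 0.98 ± 0.106 (adjusted p = 2.83e-06; -0.86 with the block). The proliferation marker MKI67 was at 0.54 ± 0.187 (adjusted p = 0.0387) and at 0.13 (adjusted p = 0.788) with the block, and PLK1, a mitotic kinase, at 1.49 (adjusted p = 0.00993) and 0.03 (adjusted p = 0.972). MKI67 lost its call when any 1 array other than TamR1 replicate 1, TamR4 replicates 1 and 2 or parental replicates 3, 4 and 8 was left out, with adjusted p-values from 0.051 to 0.0831. The list's median was -0.26 with the block (camera adjusted p = 0.000244, and adjusted p = 0.585 with an estimated correlation), and -0.34 and -0.25 within batches 1 and 2. Without TamR4 replicate 3 or without parental replicate 1 the unblocked list call passed as well (adjusted p = 0.00218 and 0.00981).

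The remaining metabolic lists moved both ways. Of 32 glycolysis and hypoxia genes 6 rose and 6 fell (6 and 7 adjusted over the list alone; median 0.03, camera adjusted p = 0.278; 0.05 with the block and 0.03 and 0.03 within batches), among them the aldolase ALDOC at 1.32 ± 0.133 (adjusted p = 1.4e-06) and NDRG1 at -1.30 ± 0.137 (adjusted p = 2.33e-06). PDK4, an inhibitory kinase of pyruvate dehydrogenase, rose by 0.97 ± 0.161 (adjusted p = 0.000251; 1.32 with the block), but without TamR8 in the average it was at 0.39 (adjusted p = 0.101). Of 29 oxidative phosphorylation genes 8 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.06, camera adjusted p = 0.762; -0.04 with the block and 0.04 and -0.15 within batches), with COX6C at -0.48 ± 0.079 (adjusted p = 0.000244; -0.31 with the block). Of 31 xenobiotic metabolism and efflux genes 6 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.02, camera adjusted p = 0.0447), a call lost with an estimated correlation (adjusted p = 0.0654) and with the block (adjusted p = 0.171; median 0.08, and 0.03 and 0.04 within batches). It was also lost without parental replicate 3, 4 or 8, TamR1 replicate 3, TamR4 replicate 1 or 2, TamR7 replicate 1 or TamR8 replicate 1, with adjusted p-values from 0.0505 to 0.0659. CYP1B1, a cytochrome P450 that metabolises estrogens, rose by 2.01 ± 0.137 (adjusted p = 1.32e-08, and 2.23 with the block). The transporter ABCC3 rose by 1.56 ± 0.21 (adjusted p = 3.42e-05, and 1.62 with the block). ALDH3B2 fell by 0.67 ± 0.142 (adjusted p = 0.00206, and -0.94 with the block). The other probe set of ALDH3B2 was at 1.06 (adjusted p = 0.131) without and -0.86 (adjusted p = 0.0505) with the block. The mean of both was at 0.196 without the block.

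Stress, death and stem cell lists were likewise mixed. Of 30 unfolded protein response genes 3 rose and 8 fell (3 and 8 adjusted over the list alone; median -0.09, camera adjusted p = 0.713; -0.05 with the block and -0.09 and -0.03 within batches). CHAC1, a target of the integrated stress response, fell by 1.18 ± 0.168 (adjusted p = 5.93e-05; -0.89 with the block), and CALR, a chaperone, was at 1.46 (adjusted p = 0.00152) without and 0.57 (adjusted p = 0.25) with the block. A brighter probe set of CALR (mean 10.99) was lower (-0.64, adjusted p = 0.0192; 0.05 with the block), so its direction is not settled. Of 27 p53 target and apoptosis genes 5 rose and 4 fell (6 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.203), and with the block the median was 0.24 (camera adjusted p = 0.00167, and adjusted p = 0.0874 with an estimated correlation), against 0.21 and 0.25 within batches. The death receptor FAS rose by 2.26 ± 0.209 (adjusted p = 5.06e-07; 2.34 with the block). FAS, ACTA2, LIPA, IFIT1, IFIT2, IFIT3 and IFIT5 lie together in a run of neighbouring genes in TamR4, TamR7 and TamR8. The median blocked differences of these runs were 0.19, 0.64 and 0.80. The changes of these genes may therefore not be separate observations. In TamR1, where FAS was at 2.04 and ACTA2 at 1.87, they lie in no such run. Of 22 stem cell genes 5 rose, SOX2 among them, and 5 fell (6 and 6 adjusted over the list alone; median 0.02, camera adjusted p = 0.428; 0.09 with the block and 0.12 and 0.26 within batches), with SOX9 at -1.50 ± 0.228 (adjusted p = 0.000116; -1.01 with the block).

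Of 29 NF-kB and cytokine genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.02, camera adjusted p = 0.053; 0.02 with the block and 0.03 and 0.04 within batches). The list passed when parental replicate 1, 2, 7 or 8, TamR1 replicate 1, TamR4 replicate 1 or 2, TamR7 replicate 2 or TamR8 replicate 2 was left out, with adjusted p-values from 0.0258 to 0.0487. IL24 fell by 1.29 ± 0.15 (adjusted p = 6.71e-06; -0.96 with the block), LCN2, an iron-binding lipocalin, rose by 0.75 ± 0.132 (adjusted p = 0.000443; 0.61 with the block), and IL1A was at 1.04 (adjusted p = 0.0175) without and -0.12 (adjusted p = 0.747) with the block. Of 17 cancer-testis antigen genes 4 fell and 13 did not pass (3 fell adjusted over the list alone; median -0.10, camera adjusted p = 0.278; -0.07 with the block and -0.03 and -0.17 within batches), including PRAME at -0.63 ± 0.125 (adjusted p = 0.00125), which was at -0.44 (adjusted p = 0.0975) with the block. Markers of non-epithelial cells gave 2 rises and 4 falls in 27 genes (3 and 6 adjusted over the list alone; median -0.10, camera adjusted p = 0.914; -0.07 with the block and -0.03 and -0.09 within batches). CD36, which adipocytes, macrophages and endothelium also express, belongs to this list, and the other 26 markers had a median difference of -0.11 (median absolute deviation 0.18) and a highest difference of 0.48.

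Each resistant line was next compared with the parental line, to ask what the separately derived lines have in common. TamR1 had 1763 called genes, 490 of them at 2-fold or more (1593 and 472 with the block). LIMCH1, which binds non-muscle myosin, rose by 4.99 ± 0.148 (adjusted p = 3.44e-13; 5.08 with the block), ahead of SOX2 (3.96), SH3BGRL (3.44), EPAS1 (3.39) and GOLM1 (3.33). After GREB1 (-6.98) the largest falls were those of NPY1R, a neuropeptide Y receptor that estrogen induces (-5.87 ± 0.495, adjusted p = 5.16e-07; -5.46 with the block), PGR (-5.51), IL20 (-5.19) and GFRA1 (-4.77). IGF1R fell by 2.15 here. Estrogen-induced genes fell in 21 of 41 cases (25 adjusted over the list alone; median -0.80, camera adjusted p = 4.88e-11, and adjusted p = 0.0379 with an estimated correlation), with medians of -0.73 with the block (adjusted p = 0.0922 with an estimated correlation) and -0.74 and -0.67 within batches. Cholesterol synthesis genes rose in 7 of 19 cases (median 0.51, camera adjusted p = 1.18e-09, and adjusted p = 0.0379 with an estimated correlation). Their median was 0.53 with the block (adjusted p = 0.0922 with an estimated correlation) and 0.53 and 0.45 within batches. Of the interferon-stimulated genes HERC5 fell (-1.39, adjusted p = 0.00739) and the other 36 did not pass. Their median was 0.25 (camera adjusted p = 0.0926), 0.25 with the block, 0.48 within batch 1 and -0.50 within batch 2. Without parental replicate 1, 2 or 8 or without TamR1 replicate 3 the list call passed, with adjusted p-values of 0.00151, 0.0167, 0.00802 and 0.00299. The number of genes called in TamR1 was 648 without TamR1 replicate 2 and 860 without TamR1 replicate 3.

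TamR4 had 2837 called genes, 715 of them at 2-fold or more (2406 and 619 with the block). CD36 (5.48 ± 0.366, adjusted p = 1.78e-08), SOX2 (5.17), IFI27 (4.49) and IFI44L (4.26) led the rises, with blocked values of 5.56, 5.51, 4.36 and 4.12. GREB1 (-6.91), COL12A1 (-5.70 ± 0.273, adjusted p = 3.58e-10; -5.72 with the block), IGF1R (-5.28), PGR (-5.14) and ELOVL2 (-4.87) led the falls. RERG fell by 3.06 here and lies in a run of 28 neighbouring genes with a median blocked difference of -0.61. Interferon-stimulated genes rose in 32 of 37 cases (35 adjusted over the list alone; median 1.81, camera adjusted p = 3.6e-27, and adjusted p = 0.143 with an estimated correlation). Their median was 1.84 with the block, 2.42 within batch 1 and 0.98 within batch 2. Cell cycle genes fell in 19 of 40 cases (22 adjusted over the list alone; median -0.63, camera adjusted p = 5.08e-10, and adjusted p = 0.39 with an estimated correlation). The transcription factor FOXM1 fell by 1.45 (adjusted p = 0.000113), CDK1 by 1.34 (adjusted p = 5.91e-05) and TYMS by 1.31 (adjusted p = 1.29e-05), with blocked values of -1.58, -1.20 and -1.22. FOXM1 lies in a run of 15 neighbouring genes with a median blocked difference of -0.58 in this line. The median of the cell cycle list was -0.74 with the block and -0.86 and -0.65 within batches 1 and 2. Without TamR4 replicate 2 the line had 1497 called genes.

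TamR7 had 3008 called genes, 1014 of them at 2-fold or more (1497 and 699 with the block), the most of any line without the block. EDIL3, an integrin ligand of the extracellular matrix, rose by 5.30 ± 0.341 (adjusted p = 1.77e-08; 5.99 with the block), and the interferon-stimulated genes OAS2 (5.16), IFI44L (5.10) and RSAD2 (4.58) rose with CD36 (4.90). With the block these were at 4.66, 4.88, 4.92 and 5.03, and against the single parental array of batch 2 at 3.53, 3.29, 4.54 and 4.98. IFI44L lost its call when either TamR7 array was left out (adjusted p = 0.0549 and 0.0666). GREB1 (-7.08), PGR (-5.60), IGF1R (-5.45), GFRA1 (-5.28) and IL20 (-5.07) fell most. Interferon-stimulated genes rose in 35 of 37 cases (35 adjusted over the list alone; median 2.91, camera adjusted p = 2.13e-39, and adjusted p = 0.0271 with an estimated correlation). With the block their median was 2.77 (adjusted p = 0.0764 with an estimated correlation), and it was 1.84 within batch 2. Antigen presentation genes rose in 16 of 21 cases (median 1.27, camera adjusted p = 1.33e-21; 1.16 with the block and 1.14 within batch 2), a call that held with an estimated correlation both without (adjusted p = 0.00728) and with the block (adjusted p = 0.0392). NF-kB and cytokine genes rose in 7 of 29 cases and fell in 1 (median 0.19, camera adjusted p = 0.000116, and adjusted p = 0.0271 with an estimated correlation; 0.16 with the block, where adjusted p = 0.109 with an estimated correlation, and 0.18 within batch 2), among them the chemokine CCL5 (1.46, adjusted p = 1.63e-05) and LCN2 (1.70, adjusted p = 4.9e-05). Without TamR7 replicate 1 the line had 798 called genes, 563 of them at 2-fold or more, and without TamR7 replicate 2 it had 1118 called genes.

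TamR8 had 2009 called genes, 743 of them at 2-fold or more (1408 and 661 with the block). CD36 (6.30 ± 0.427, adjusted p = 2.66e-08), PPP1R9A (5.21), SOX2 (4.85), SAMD9 (4.25) and TNFRSF11B, a decoy receptor for the ligand RANKL (4.06), rose most, with blocked values of 6.43, 5.59, 5.39, 4.55 and 3.85. CD36, PPP1R9A and SAMD9 belong to a run of 74 neighbouring genes with a median blocked difference of 1.09 in this line. GREB1 (-6.97), PGR (-5.63), IL20 (-5.45), IGF1R (-5.43) and GFRA1 (-4.98) fell most, and TFF1 fell by 3.85 (adjusted p = 9.24e-11; -3.87 with the block). PDK4 rose by 2.72 (adjusted p = 2.67e-06; 3.15 with the block), and SDHA, a subunit of succinate dehydrogenase, by 1.26 (adjusted p = 4.81e-05; 0.98 with the block), SDHA lying in a run of 76 neighbouring genes with a median blocked difference of 1.14. Cholesterol synthesis genes rose in 7 of 19 cases (11 adjusted over the list alone; median 0.72, camera adjusted p = 4.75e-11, and adjusted p = 0.0164 with an estimated correlation). Their median was 0.48 with the block (adjusted p = 0.211 with an estimated correlation) and 0.54 within batch 2. Interferon-stimulated genes rose in 8 of 37 cases (13 adjusted over the list alone; median 1.07, camera adjusted p = 4.75e-11, and adjusted p = 0.308 with an estimated correlation), and their median was 0.79 with the block and 0.17 within batch 2. Without TamR8 replicate 1 the line had 510 called genes, 413 of them at 2-fold or more, and without TamR8 replicate 2 it had 580 and 432.

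In all 4 lines 88 genes were higher and 69 lower by 2-fold or more (97 and 33 with the block), of which 59 and 33 were so both with and without the block. Both sets held GREB1, PGR, IGF1R, CD36, SOX2, TIMP2 and EPAS1 in their respective directions. Data simulated without any line effect but with shared parental arrays gave 0 genes in either direction, with or without a batch shift of the size fitted to the real arrays. Those data hold no changed gene, so they do not show how much sharing lines with effects would have. Independent lists would share 0.00388 and 0.000985 genes. With the parental arrays split between the lines the numbers were 45 (35 to 61 over 20 draws) and 39.5 (35 to 51). Across genes, which are not independent replicates, the differences of 2 lines from the parental line correlated at r = 0.66 for TamR1 and TamR4 to 0.78 for TamR4 and TamR7. Simulated lines without effect correlated at 0.20 to 0.27 with shared parental arrays alone and at 0.71 to 0.80 when the batch shift was added. The unblocked r exceeded the simulated r with the batch only for TamR4 and TamR7 (0.78 against 0.75). The simulated lines lack the differences between real lines, which lower r. The comparison of r therefore does not show how much of it the batch gives. The unblocked covariances of 0.124 to 0.196 stood against 0.042 to 0.099 in the simulations with the batch. With the block r was 0.63 to 0.76 against 0.43 to 0.49 in the simulations, and the covariances were 0.108 to 0.164 against 0.0129 to 0.0236. With split parental arrays r was 0.52 to 0.68. Without parental replicate 8 the number higher in all lines was 135, and without TamR8 replicate 1 it was 59.

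The lines also differed from one another. The F-test called 1245 genes (2103 with the block), and the widest ranges among the leading genes were those of OAS2 (5.44), LIMCH1 (5.0), CRISP3 (4.96), EDIL3 (4.81), RSAD2 (4.68), PCDH7 (4.66), SLITRK6 (4.61), SLC6A14 (4.55), ANKRD30A (4.53) and TNFRSF11B (4.39). OAS2, an antiviral synthetase, was highest in TamR7 and lowest in TamR1. CRISP3, a secreted glycoprotein, and SLC6A14, an amino acid transporter, were 3.90 and 3.98 above the parental line in TamR8, and SLITRK6 was 3.32 below it there. PCDH7, a protocadherin, was 3.69 below the parental line in TamR4, and ANKRD30A, a breast differentiation antigen, 3.03 below in TamR8 but 1.5 above in TamR1. By pairs, 238 genes differed between TamR4 and TamR7 and 720 between TamR1 and TamR4, the lowest and highest numbers of the 6 pairs without the block. With the block these numbers were 370 and 1260. Of the 238 and 720 genes, 151 and 295 differed by 2-fold or more. At 2-fold or more the highest number was that of TamR1 and TamR7 (337), and with the block that of TamR7 and TamR8 (398). The pairs also differ in their numbers of arrays, so their counts do not rank the lines by distance. Interferon-stimulated genes were lower in TamR1 than in TamR7 by a median of 2.60 (camera adjusted p = 6.51e-53 over all lists and pairs), a call lost with an estimated correlation (adjusted p = 0.0652). Antigen presentation genes were lower in TamR1 than in TamR7 (median -0.76, camera adjusted p = 8.99e-23, and adjusted p = 0.032 with an estimated correlation), and with the block and an estimated correlation the adjusted p was 0.18. Without TamR7 replicate 1, TamR8 replicate 1 or TamR8 replicate 2 the F-test called 721, 727 and 774 genes.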

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

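The tests of the array batch as the whole cause of the average calls, of the batch behind the interferon list in TamR4, TamR7 and TamR8, of variation between cultures for TamR4 and TamR8, and of TamR1 and TamR4 by splits inside batches were chosen only after the results had been seen.

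The first pattern was the set of 620 genes called at 2-fold or more between the average of the resistant lines and the parental line. The array batch was excluded as its whole cause, since 54.5% of these genes were called at 2-fold or more in the same direction with the batch as a block. As part of the cause the batch stays open and may account for some of the calls: across genes, the difference of TamR7 and TamR8 from parental replicates 1 to 7 correlated at r = 0.42 with the difference between batches inside TamR1 and TamR4, against r = -0.19 for their difference from parental replicate 8 inside batch 2. A chance division of the arrays was excluded, because 1 of 100 splits, the real one, gave 620 genes and the highest other gave 113. With splits inside batches and the block 1 of 100, again the real one, gave 492 genes, and the highest other gave 9. Resistance itself and the presence of tamoxifen, which go together here, remain as untested biological explanations.

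The comparisons of TamR1 and TamR4 with the parental line were put through the same splits, each with only that line and the parental arrays in the fit. For TamR1, 1 of 100 splits, the real one, gave 457 genes at 2-fold or more, and the highest other gave 10. For TamR4, 1 of 100 splits, the real one, gave 676 genes, but the highest other gave 467. That split set TamR4 replicates 2 and 3 and parental replicate 8, which are the batch 2 arrays, against the rest, so these splits, which cross the batches, are not used alone. With the batch as a block and splits inside the batches only, 1 of 24 splits, the real one, gave 445 genes for TamR1. The real split gave 572 for TamR4, and the highest other gave 0 for each line. A share of 1 in 24 is the lowest that these splits can give. A chance division of the arrays is thus unlikely for either line. Splits of arrays from 1 derived line cannot exclude chance differences between that line and the parental line.

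The second pattern was the higher level of interferon-stimulated genes in TamR4, TamR7 and TamR8. The batch was excluded as the whole cause for TamR4, where 31 of 37 genes rose with the block (median 1.84). Its batch 1 array lay 2.42 above the parental arrays of that batch, although its batch 2 arrays lay 1.44 and only 0.59 above the parental array there. TamR7's arrays lay 1.84 and 1.89 above the same parental array, past a cut of 2 SD (SD 0.70, parental arrays of batch 1). However, the parental arrays of batch 1 alone ran from -0.61 to 1.27 around their mean, and batch 2 has a single parental array. The batch was therefore not excluded for TamR7. TamR8's arrays lay 0.33 and 0.06 above that single parental array, so the batch and the line cannot be told apart for TamR8, while batch 2 minus batch 1 was 0.79 in the parental line but -0.42 in TamR1 and -0.43 in TamR4. Variation between cultures of a line was measured by the largest range of the list mean within a group, 1.89 among the parental arrays, where replicates 1, 2 and 8 stood highest; the gaps of TamR4 (2.06) and TamR7 (2.9) to the parental mean exceeded it, TamR4 narrowly and with its lowest array at 9.14 against 8.88 for the highest parental array, whereas the gap of TamR8 (1.15) lay inside it, so such variation could account for TamR8. Whether the rise in TamR4 and TamR7, found and tested on the same arrays, goes with resistance, with tamoxifen in the medium or with the history of each line was not tested.

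Single parental arrays stood far from the other 7 for 13 of the 92 genes named, where the gap to the nearest array exceeded what chance allows in 1 of 20 groups, given here as a share of the group's range with the array's log2 value. Chance flags about 1 in 20 groups. Parental replicate 1 stood apart for TFF1 (0.69, at 13.96), TYMS (0.59, at 12.22), LIMCH1 (0.55, at 4.61), RSAD2 (0.72, at 6.45) and HERC5 (0.60, at 7.59). Parental replicate 8, the parental array of batch 2, stood apart for ELOVL2 (0.54, at 8.04), TM7SF2 (0.59, at 9.36), IL1A (0.57, at 6.21), PLK1 (0.60, at 8.94), CLDN3 (0.72, at 10.15) and INSR (0.68, at 6.41). Parental replicate 2 stood apart for FHL2 (0.58, at 7.73) and parental replicate 5 for CCND1 (0.56, at 10.69).

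The resistant lines differed from one another, by the F-test and with the batch as a block as well, for 48 of the 92 genes. Over all 19775 genes the F-test called 1245. Some of the 92 genes were named by this same test or for their change in a single line, so the 48 are partly fixed by that choice. The ranges between the lowest and the highest line, in log2 units, were widest for OAS2 (5.44), LIMCH1 (5.0), CRISP3 (4.96), EDIL3 (4.81), RSAD2 (4.68), PCDH7 (4.66), SLITRK6 (4.61), SLC6A14 (4.55), ANKRD30A (4.53), IFI27 (4.51), TNFRSF11B (4.39), PPP1R9A (4.36), NPY1R (4.23) and AGR3 (4.08). They were PSMB9 3.81, HERC5 3.6, PSMB8 3.58, SAMD9 3.5, COL12A1 3.34, KRT13 3.31, IGF1R 3.3, SNAI2 3.25, CD36 3.14 and TFF1 3.09 in the next group. Ranges from 2 to 3 units were found for LYN (2.78), CYP1B1 (2.6), PDK4 (2.59), FHL2 (2.41), HLA-C (2.27) and EPAS1 (2.17). The others were EPHA4 1.93, TIMP2 1.68, PGM2L1 1.61, MKI67 1.58, CCL5 1.58, BCL2 1.57, LCN2 1.5, ALDH3B2 1.47, FOXM1 1.46, SDHA 1.46, KRT15 1.4, CDK1 1.28, ATP10D 1.25, FYN 1.22, CDH3 1.15, NHERF1 1.1, RAPGEFL1 0.96 and ESR1 0.92.

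Among the gene lists, antigen presentation genes differed between TamR1 and TamR7 (median -0.76) and luminal epithelial genes between TamR4 and TamR7 (median -0.26) with the preset and with the estimated correlation, and both calls were lost with the block and an estimated correlation (adjusted p = 0.18 for each). A further 13522 probe sets had no single gene name and entered only the setting with every probe set on its own. Of these, 347 were called at 2-fold or more in the average of the resistant lines, 245 higher and 102 lower. With the batch as a block 64 of the 347 were called as well.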

How the results depend on the processing

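The settings with the batch (as a block, within batch 1, within batch 2, and as a block without parental replicates 1 and 2) were chosen only after the data had been seen. So was the setting without parental replicates 1 and 2 and without the block. Of the counts under all settings 429 stayed within 1.5 times the reported count and 80 did not, and of the values of named genes 5792 kept direction and side of the threshold, 73 newly passed it, 342 no longer passed it and 21 reversed. For gene lists these numbers were 3070, 98, 61 and 1, and an estimated correlation ended 15 of the 31 list calls without the batch block and 36 of the 37 with it. Every count that was run stayed within 1.5 times under quantile normalisation, median centring, a mean log2 of at least 5, an intensity trend with robust variances, leaving out parental replicate 1 alone or with parental replicate 2, pooled groups, leaving a line out of the average, and fits with only 1 resistant line. Of the 15 counts only 4 were run with pooled groups and with each line left out, and 2 with each fit of 1 resistant line. For the changes below the cause was not tested, except that fewer or more probe sets or arrays entered where the setting says so. Scanner output was not used and background was not analysed, so the lowest detectable level was not determined.

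With genes of a mean log2 of 7 or more, the average contrast had 2201 genes lower, TamR1 325 at 2-fold or more, and 44 were lower by 2-fold or more in all lines. With the mean of all probe sets of a gene, 127 genes were lower by 2-fold or more in the average, and 53 were higher and 43 lower in all lines. SDHC (0.117), ALDH3B2 (0.196) and CCL5 (-0.054) reversed there. With every probe set on its own, 6682 probe sets were higher and 7146 lower in the average, 1603 and 511 of them by 2-fold or more; 3314 changed in TamR1 (1173 at 2-fold or more), 4491 in TamR4 (1423), 6601 in TamR7 (2864) and 3461 in TamR8 (1606), and 179 were higher and 127 lower in all lines. With array weights 6019 genes were lower in the average, 7070 changed in TamR1 (768 at 2-fold or more), 6447 in TamR4 (1099), 6924 in TamR7 and 6598 in TamR8, 167 were higher and 139 lower in all lines, and 5126 differed between the lines. With a test beyond 2-fold, 70 genes were higher and 47 lower in the average, 62 changed in TamR1, 115 in TamR4, 136 in TamR7 and 107 in TamR8, and 7 were higher and 15 lower in all lines.

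With the replicate number as a block, 598 genes were higher by 2-fold or more in the average, 1527 changed by 2-fold or more in TamR7 and 1172 in TamR8, and 197 were higher in all lines. The numbers do not pair the arrays: the deviations of same-numbered arrays from their group means correlated at -0.22 to 0.64 (median 0, against -0.03 for different numbers), 6 of 23 such pairs exceeded 0.1, and 4 of 13 arrays were closest to one of their own number.

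With the array batch as a block, 771 genes were lower in the average (105 by 2-fold or more), 1497 changed in TamR7, 33 were lower in all lines and 2103 differed between the lines, and IL1A reversed (-0.125). Within batch 1, which has no array of TamR7 or TamR8 and where TamR1 and TamR4 have a single array each, assumed to vary like the parental arrays, 536 genes were higher and 293 lower in the mean of TamR1 and TamR4 (114 lower by 2-fold or more), 284 changed in TamR1 (244 by 2-fold or more) and 753 in TamR4; SLC6A14 (-0.439), PLK1 (-0.022), MKI67 (-0.100), SDHA (-0.215), IL1A (-0.661) and FOXA1 (-0.074) had the opposite sign there. Within batch 2, where the parental line has a single array assumed to vary like the other groups, 651 genes were higher and 299 lower in the average (86 lower by 2-fold or more), 509 changed in TamR1, 838 in TamR4, 1078 in TamR7 (623 by 2-fold or more) and 1152 in TamR8, and 27 were lower in all lines. CLDN3 (-0.081), INSR (0.227), PLK1 (-0.150), SDHA (-0.018), MAGEB2 (0.041) and the interferon list in TamR1 (-0.501) reversed within batch 2. With the block and without parental replicates 1 and 2, 1106 genes were lower in the average (120 by 2-fold or more), 41 were lower in all lines and 3313 differed between the lines, and PLK1 (-0.124) and IL1A (-0.092) reversed. Without TamR7 in the average HERC5 (-0.668) and CCL5 (-0.006) reversed, and without TamR8 SLC6A14 (-0.453) and SDHA (-0.018).

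Leaving out 1 array at a time gave 1887 to 2545 genes higher and 2566 to 4004 lower in the average, 351 to 438 and 212 to 283 of them by 2-fold or more. Genes changed ran from 648 to 2619 in TamR1 (339 to 622 by 2-fold or more), 1497 to 3658 in TamR4 (569 to 915), 798 to 4087 in TamR7 (563 to 1268) and 510 to 2910 in TamR8 (413 to 944). Genes higher by 2-fold or more in all lines ran from 59 to 135 and lower from 46 to 97, and genes differing between the lines from 721 to 1609. The lowest values for changed genes came without TamR1 replicate 2, TamR4 replicate 2, TamR7 replicate 1 and TamR8 replicate 1. The highest came without parental replicate 8, except that the 915 for TamR4 came without TamR4 replicate 1. When 1 array of TamR7 or TamR8 was left out, the remaining array was assumed to vary like the other groups.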

Other observations

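The genes named in this paragraph, and the comparisons of neighbouring genes with parental replicate 8 and with the other lines, were chosen only after the results had been seen. Beyond the genes described above, the 59 genes higher by 2-fold or more in all resistant lines both with and without the batch as a block held GBP1, GBP2 and GBP3, which encode interferon-inducible guanylate-binding proteins. They also held the complement component C3 and the complement inhibitor CD59, LIPA, the lysosomal acid lipase, KYNU, an enzyme of tryptophan breakdown, PRKCA, which encodes protein kinase C α, L1CAM, a neural adhesion molecule, and SALL4, a transcription factor of pluripotent cells. The 33 genes lower in all lines with and without the block held TFF3, a secreted trefoil peptide, CXCL12, a chemokine, FGFR4, a fibroblast growth factor receptor, MGP, the matrix Gla protein, and ABCG1, a transporter that exports sterols.

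Genes that changed lay beside one another more often than chance placed them. In the gene order of GRCh38.p14, over 13860 genes with a mean log2 of at least 5, 286 windows of 15 neighbouring genes had a median blocked difference beyond the 95th percentile of the highest windows in 200 permutations of the order, with 25 in TamR1, 72 in TamR4, 58 in TamR7 and 131 in TamR8. A hypothesis is that regional changes, such as copy number changes, may have moved these genes together, but the 286 windows show only that neighbours changed together, which any cause of shared change would give. Families of genes with similar names were excluded as the whole cause, since 261 windows were found when each name stem was represented by 1 gene. Single runs, such as that of TamR1 from ZNF101 to ZNF43, were not judged in this way, and relatives with unlike names were kept. DNA was not measured, so copy number was not tested and the cause stays open.

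In TamR8, 76 neighbouring genes from CCDC127 to IL7R, SDHA among them, had a median blocked difference of 1.14, and 74 from PMS2P5 to SMURF1, with CD36, SAMD9 and PPP1R9A, had a median of 1.09. Inside batch 2 these medians were 1.08 and 1.08 against parental replicate 8, and 1.09 and 0.94 against the other resistant lines. In the first run 60 genes and in the second 67 had the sign of the median. In TamR4, 28 genes from FAM234B to ETNK1, RERG among them, had a median of -0.61, and -0.61 against the other lines. Most runs did not set their line apart: in 18 of 29 the difference from the other lines inside batch 2 was under 50% of the blocked median, which held for all 4 runs of TamR1, 5 of 10 in TamR4, 6 of 8 in TamR7 and 3 of 7 in TamR8. Of the 29 runs 14 shared genes with a run of another line, and every comparison with the parental line here rests in part on parental replicate 8. Neighbouring genes correlated at r = 0.16 in TamR1 to 0.224 in TamR8, against at most 0.026 in permuted orders.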
